A study of Caenorhabditis elegans with 2 samples.

How the data were processed

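The data are peak lists from chromatin immunoprecipitation and sequencing of eGFP-tagged CEH-28 in whole L3 larvae, with pooled sexes, in 2 biological replicates of 1 group. Per the labels, library fragments had a size range of 150 to 350 bp. The group and the replicate numbers were taken from the labels, and there was no comparison group. The peak caller, the aligner and their versions are not given in the sources used here.

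The deposited files are a relaxed peak list for each replicate, made from that replicate and a control, a relaxed list made from both replicates pooled, and a thresholded list derived from these 3 by the irreproducible discovery rate, per the deposited file records. Each peak has a signal value and a −log10 q-value as the authors' peak caller gave them, both used here as deposited. The signal is the authors' own value per peak, and it served only to describe, rank or filter peaks within a list. The −log10 q-value reached the same highest value in 84.8% of the thresholded peaks, so peaks were ranked by signal. Relaxed lists held 30000 peaks each, and with lists of a fixed length their size carries no information. In the thresholded list 78 peaks repeated the interval of another peak with a different summit, and each was kept. In the replicate 2 list 1 summit lay at the end of its interval plus 1 bp and was set to the last base. Coordinates are on ce11, counted from 1. A ce10 version of the thresholded list was used for its count alone. No read counts are given in the lists, so depth is unknown, and intervals printed here cover counting error of peaks, windows or genes only. Because control reads entered peak calling, extra copies of the transgene regions in both samples may not appear as signal.

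Gene positions were taken from Ensembl release 115 and genome sequence from the same assembly. A promoter window ran from 1000 bp upstream to 200 bp downstream of each annotated 5' end of a protein-coding gene. A gene can have several such ends, so a summit in a window can lie inside the gene, as at cox-6B, pbrm-1, sma-9, peb-1 and lit-1. Many worm transcripts are trans-spliced, so that annotated 5' ends can lie downstream of the start of transcription. Summits in these windows were counted against 1000 sets of random positions with the same number per chromosome. Replicates were compared by overlap of at least 1 bp between their strongest peaks, as many as the thresholded list holds, against 1000 circular shifts of replicate 2, and by Spearman's rho with 100000 permutations. Shares of peaks on X were tested with an exact binomial test, and shares in the outer 25% of chromosomes at each end against random positions, drawn inside or outside promoter windows where summits were divided by them. A permutation p for a location or an overlap is the two-sided share of these random placements or shifts at least as extreme as the data. Sequence motifs were counted on both strands within 50 bp of the summit and in windows of the same size 500 bp to each side. The windows were pooled over peaks, so the pairing of a summit with its own flanks was not used in the tests. Odds ratios from all 7-mers and their rearrangements had a pseudocount of 0.5 added to each count. Motifs, gene lists, non-coding RNA classes and strong against weak peaks were tested with Fisher's exact test, two-sided, with conditional odds ratios and exact 95% intervals. Families of tests were adjusted after Benjamini and Hochberg at 0.05. Peaks and genes are not independent replicates, and all p-values describe the peaks of these 2 replicates.

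Before the data were examined, 29 gene lists, the tests and the rule for named genes were fixed. Genes named were those of the 20 strongest thresholded peaks that overlapped a strong peak of both replicates and had a summit in the promoter window of a gene with a symbol, taken as a gene name of letters and a number, every gene of the list of CEH-28 targets and M4 genes, the 3 members of every other list with the highest signal, and ceh-28 and unc-119. Where a count was 5 or fewer all members were named. Other peaks described were chosen after their values were seen. The scan of 7-mers and the tests of AATCGAT, AATCRAT, CTGCGTC, GCGCAGGG and CGCGCAG were added after the data were examined. So were the division of arms by location and by chromosome end, the filter on copies between the windows and the comparisons of the 100 strongest peaks.

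Alternatives fixed beforehand were each replicate alone, the thresholded peaks above the median signal, promoter windows of 500 bp upstream to 100 bp downstream and of 2000 bp upstream to 200 bp downstream, other backgrounds, other window sizes, other overlap rules, assignment to the nearest 5' end, and 10000 circular shifts of list membership along the gene order. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The tests were checked on simulated data. For a simulated list of 200 genes bound at 4 times the odds among 19973 genes, the gene list test gave an odds ratio of 4.07 (95% interval 2.98 to 5.51), and 0 of 200 random lists passed. For AATCGAT written at 28.9% of 3531 random positions, the motif test found it at 30.6%, where 2.46% had it before.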

Results

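Sites bound by an eGFP-tagged CEH-28 protein were mapped by chromatin immunoprecipitation and sequencing in whole L3 larvae of Caenorhabditis elegans. CEH-28 is a homeodomain protein of the NK-2 class, known from the M4 neuron of the pharynx. The strain carried an integrated transgene with tagged ceh-28 in a background with a mutation in unc-119. There was 1 group with 2 biological replicates and no comparison group, so the comparisons were made between replicates, between parts of the genome and between sets of genes. Read depth is unknown, because the peak lists give no read counts. All positions are on ce11.

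The thresholded list held 3531 peaks, with a median length of 400 bp and a signal from 65.9 to 5643. These were the 3531 peaks of highest signal in the pooled list of 30000. The strongest peak lay on chromosome X from 8036001 to 8036973, in intergenic sequence 4821 bp from the nearest protein-coding gene, C34D10.1, and within 500 bp of a tRNA gene, and it ranked 1 in both replicates. The next peaks by signal were also on X, from 11093842 to 11094502 with a signal of 3660, and from 11937220 to 11937867 with a signal of 2606. The strongest autosomal peaks lay in an intron of ugt-31, a UDP-glucuronosyltransferase gene (chromosome I, 2334557 to 2335902, signal 2302), and in an intron of mac-1 (chromosome II, 13315471 to 13316678, signal 2210). These 5 peaks were chosen for description after their values were seen.

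The replicates shared most of their strong peaks. Of the 3531 strongest peaks of replicate 1, 2653 overlapped 1 of the 3531 strongest of replicate 2 by at least 1 bp (75.1%, 95% Wilson interval 73.7% to 76.5%). Circular shifts of replicate 2 along each chromosome gave 2.79% on average and 4.73% at most (permutation p = 0.002, two-sided, the smallest that 1000 shifts can give). Among thresholded peaks, 3068 overlapped a strong peak of replicate 1, 3019 one of replicate 2, and 2603 one of each (73.7%). Across 3513 thresholded peaks with a partner in both replicate lists, the signal in replicate 1 and replicate 2 had a Spearman rho of 0.73 (permutation p = 2e-05, the smallest that 100000 permutations can give). This correlation is across peaks, which are not independent replicates, and the thresholded list was itself made from both replicates.

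Promoters of protein-coding genes held 1863 of the 3531 summits (52.8%, 95% Wilson interval 51.1% to 54.4%). Random positions on the same chromosomes gave 25.8% (permutation p = 0.002, two-sided, the smallest that 1000 random sets can give). Coding exons outside promoter windows held 62 summits, or 1.76%, where random positions gave 18.9%. Introns held 762 summits and intergenic sequence 699, at 0.765 and 0.819 of the random share. Both classes exclude promoter windows, so a high promoter share by itself lowers these ratios. Promoter binding was less frequent among the strongest peaks. In the upper 25% by signal 412 of 882 summits lay in promoter windows (46.7%), and in the lower 25% it was 473 of 882 (53.6%), with an odds ratio of 0.758 (95% interval 0.626 to 0.918, Fisher's exact test, two-sided, p = 0.00426). Of the 100 strongest peaks, 46 lay in introns, 25 in intergenic sequence and 24 in promoter windows.

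The strongest promoter peaks lay at genes of varied function. The rule fixed before the data were examined took 20 promoter peaks of genes with a symbol, found among the strong peaks of both replicates, and these served 22 genes. The highest of these was at nspc-17 on X, with a signal of 2022 and its summit 759 bp upstream of the 5' end. A promoter peak at Y48C3A.18, with a signal of 1952, was not taken because the gene has no symbol. The next under the rule were at clp-6, a calpain gene on chromosome IV (signal 1379), tasp-1, a threonine aspartase gene on III (1317), and cox-5A, a cytochrome c oxidase subunit gene on III (1198). The peak of ins-39, an insulin-like peptide gene on X, had a signal of 1127. A peak with a signal of 1077 on III lay between drr-2 and set-16, a histone methyltransferase gene, and one of 756 on II lay between cap-2, an actin capping subunit gene, and gmps-1, a GMP synthase gene. Chromatin genes in the set also included bet-2 (signal 952) and pbrm-1 (signal 932), which both encode bromodomain proteins. Ribosomal protein genes were represented by rpl-3 (signal 890), rpl-20 (signal 750) and rpl-35 (signal 715). The others were rexd-1 (signal 800), zhp-4 (signal 796), cdc-48.1 (signal 726), gei-4 (signal 701), dyb-1 (signal 668), sor-1 (signal 666), ubc-25 (signal 637) and wwp-1 (signal 631).

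Autosomal arms together held many of the peaks that lay outside promoters, though not at every end. In the outer 25% at each end of the chromosomes lay 54.9% of all summits, against 50% of random positions (permutation p = 0.002, two-sided). When summits were divided after the data were examined, the arms held 68.4% of the 1391 autosomal summits outside promoter windows, where random positions outside these windows gave 51.9% (permutation p = 0.002). They held 45.2% of the 1590 autosomal promoter summits, where random positions in promoter windows gave 45.0% (permutation p = 0.961). Single ends differed. Among summits outside promoters the left 25% of chromosome III held 50.1% and that of IV 46.3%, and the right 25% of V 48.6%, whereas the left 25% of V held 12.5% and the right 25% of IV 19.2%. On X the arms held 49.1% of 550 summits (permutation p = 0.68). Chromosome III had the most peaks per Mb, at 50.4, and chromosome V the fewest, at 24.1. Of the 100 strongest peaks, 83 lay in arms.

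**Figure D1:**
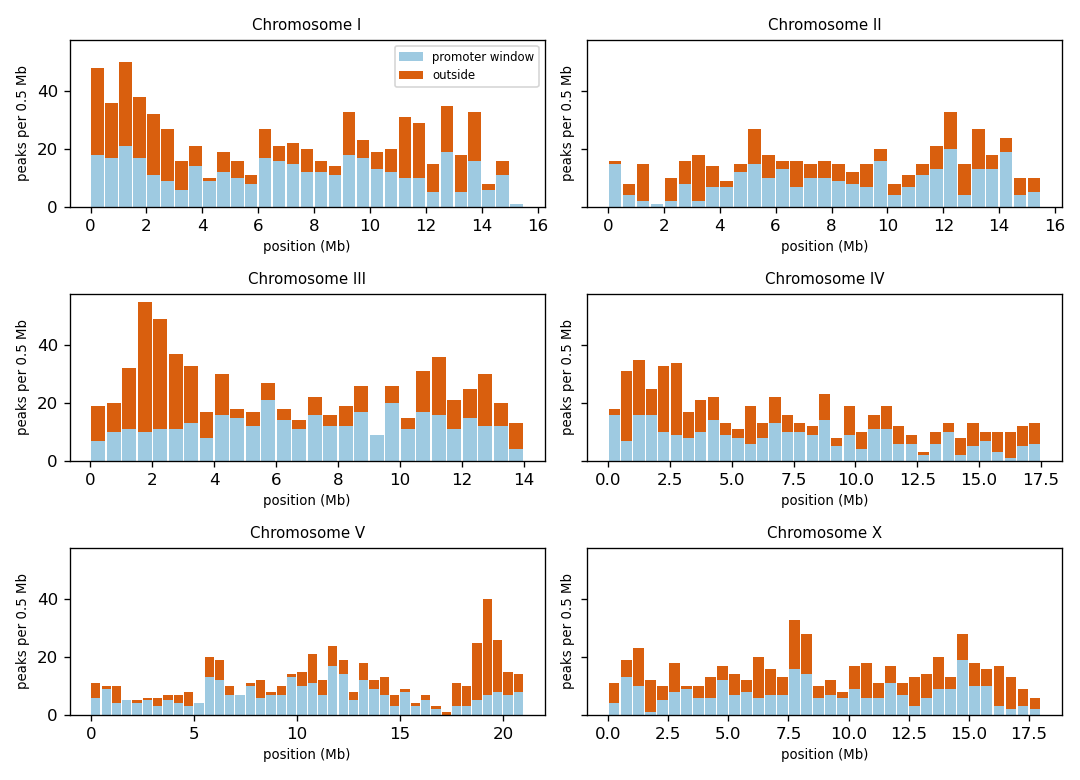
Thresholded peaks per 0.5 Mb along each chromosome, with position in Mb on the horizontal axis and summits in and outside protein-coding promoter windows stacked. The last bin of a chromosome covers less sequence than the others. Summits outside promoters gather toward some ends of the autosomes, such as the left of III and the right of V, and not toward others, such as the left of V.

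Chromosome X held 550 peaks, or 15.6% of the list (95% Wilson interval 14.4% to 16.8%), where its share of the assembly is 17.7% (binomial test, two-sided, p = 0.00101). The X share was uneven along the list. The 5 peaks of highest signal and 10 of the top 20 were on X, and the top 100 held 21 X peaks, against 15.4% of the others (odds ratio 1.46, 95% interval 0.848 to 2.41, Fisher's exact test, two-sided, p = 0.16, chosen after the data were examined). In the upper 25% by signal, though, 113 of 882 peaks were on X (12.8%), and the share was 16.2%, 16.2% and 17.1% in the following 25% steps. The deficit was also found in replicate 1 alone (14.5%, exact binomial p = 3.80e-07) and in the peaks above the median signal (14.5%, exact binomial p = 0.000417). The deficit on X depended on the background, since X holds 14.8% of promoter window sequence, and against that share the peaks on X were not fewer (exact binomial p = 0.169). It also missed the threshold in replicate 2 alone, where the X share was 16.5% (exact binomial p = 0.0813).

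The sequence bound by NK-2 class proteins, TYAAGTG (Y is C or T), was rare at the summits. It occurred within 50 bp of 46 of 3531 summits (1.30%) and in 133 of 7062 windows centred 500 bp to either side (1.88%), with an odds ratio of 0.688 (95% interval 0.479 to 0.971, Fisher's exact test, two-sided, p = 0.0306). Among 7-mers made of the same bases, 38.5% of the 629 rearrangements of TCAAGTG and 48.3% of the 209 rearrangements of TTAAGTG had a smaller odds ratio than the motif. The deficit was not past the threshold with windows of 25 bp (odds ratio 0.861, exact p = 0.561) or 100 bp (0.845, p = 0.139) on each side, in the peaks above the median signal (0.684, p = 0.135), or in replicate 1 alone (0.893, p = 0.522). For promoter summits against promoters without a peak the odds ratio was 0.423 (exact p = 0.00247).

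Other sequences were frequent at the summits. In a scan of all 8192 7-mers, added after the strongest peaks had been examined, AATCGAT had the lowest p. It lay within 50 bp of 1247 summits (35.3%) and in 490 of 7062 flanking windows (6.94%), an odds ratio of 7.32 (95% interval 6.52 to 8.23, Fisher's exact test, two-sided, adjusted p = 4.45e-282). The related AATCAAT occurred at 878 summits (24.9%, odds ratio 4.38), and CTGCGTC at 302 summits (8.55%, odds ratio 11.7, 95% interval 8.74 to 15.9). Chosen anew on chromosomes I, II and III, the leading 7-mer was again AATCGAT, and on IV, V and X together it had an odds ratio of 6.93 (95% interval 5.75 to 8.39, exact p = 3.51e-107).

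**Figure D2:**
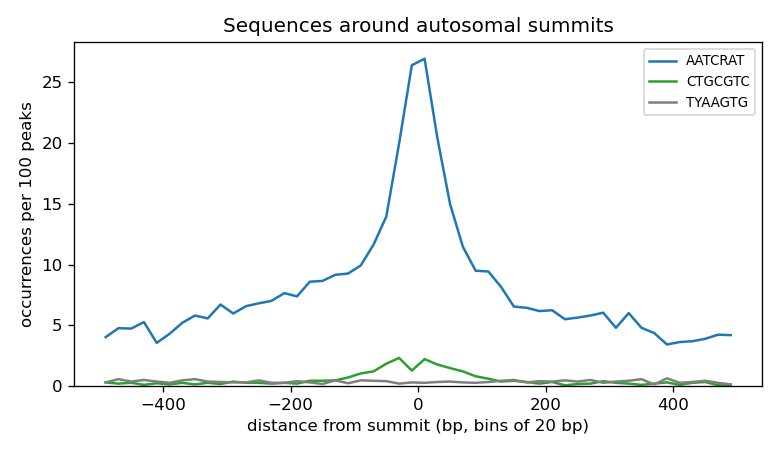
Occurrences per 100 autosomal peaks of AATCRAT (R is A or G), CTGCGTC and TYAAGTG in bins of 20 bp, against distance from the summit in bp. AATCRAT rises toward the summit and TYAAGTG does not.

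AATCRAT, which joins AATCGAT and AATCAAT, was found more often outside promoters and on autosomes, both at summits and in their flanks. On autosomes it lay at 887 of 1391 summits outside promoter windows (63.8%) and 623 of 1590 promoter summits (39.2%), an odds ratio of 0.366 for promoters (95% interval 0.315 to 0.426, Fisher's exact test, two-sided, p = 3.84e-41). On X it lay at 162 of 550 summits (29.5%), against 50.7% on autosomes (odds ratio 0.407, exact p = 2.42e-20). Flanking windows had it in 6.27% on X and 13.3% on autosomes, and over all chromosomes in 9.34% around promoter summits and 15.3% around others. The odds ratio over flanks was 6.23 on X and 6.72 on autosomes, and 5.91 for promoter summits and 7.62 for others. For AATCGAT alone it was 13.5 on X and 7.26 on autosomes. Copies within 200 bp of the summit went with signal across 2981 autosomal peaks (Spearman rho 0.29, permutation p = 2e-05), and not detectably across 550 X peaks (rho 0.05, permutation p = 0.203). The rho was 0.45 for autosomal peaks outside promoters and 0.12 for those in promoters. Autosomal peaks with 0, 1, and 2 to 3 copies had median signals of 99.9, 101.4 and 99.6, and those with 4 or more 209.3. Among the 200 strongest autosomal peaks, 134 had 4 or more copies (67.0%), against 17.8% of the others. The peak in the intron of ugt-31 had 17 copies, and the first of the 2 summits in mac-1 had 15. Copies were matches on either strand, and overlapping matches on opposite strands may each count as a copy. The numbers of copies, and the classes made from them, therefore need not be numbers of separate sites.

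Some of the strongest X peaks carried another sequence. GCGCAGGG lay within 50 bp of the summit in 14 of the 100 strongest X peaks and in 2 of the other 450 X peaks (odds ratio 36.1, 95% interval 8.07 to 333, Fisher's exact test, two-sided, p = 1.70e-09), and in 0 of 2981 autosomal peaks. Of the 20 strongest X peaks, 11 carried it. AATCRAT lay at 39 of the same 100 peaks (odds ratio over flanks 10.9) and CTGCGTC at 16, with 0 of 200 flanking windows. Among them were the peaks at 8036001 to 8036973 and 11093842 to 11094502, the intergenic peak at 4208589 to 4209602 (signal 2192, 1321 bp from hpk-1), the promoter peak of nspc-17 and a peak in an intron of mom-1 at 6296261 to 6296937 (signal 1642). These tests were added after the strongest peaks had been examined, and the odds ratio ranged from 17.7 in replicate 2 alone to 71.6 in replicate 1 alone.

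**Figure D3:**
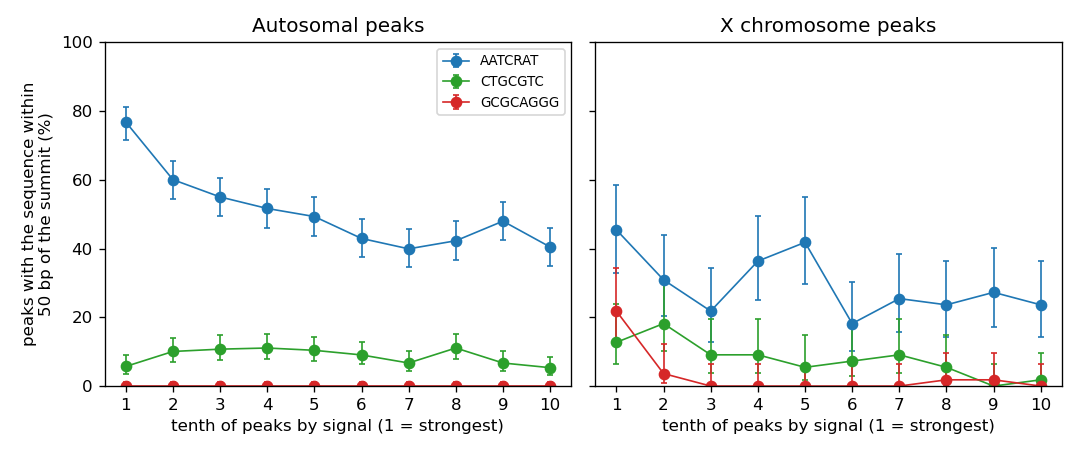
Share of peaks (%) with AATCRAT, CTGCGTC or GCGCAGGG within 50 bp of the summit, in 10 bins of equal size from the strongest to the weakest signal, on autosomes (left) and X (right). Bars are 95% Wilson intervals. AATCRAT falls from the strongest autosomal peaks to the weaker ones, and GCGCAGGG is found at X peaks and at 0 autosomal peaks.

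Genes of protein synthesis, respiration and protein folding had promoter peaks far more often than other genes. In the gene lists, a gene is called bound where a summit lay in its promoter window. A summit lay in the promoter window of 2240 of 19973 protein-coding genes (11.2%). Of 77 ribosomal protein genes 55 had one (71.4%, odds ratio 20.3, 95% interval 12.1 to 35.0, exact adjusted p = 3.64e-34), led by rpl-3, rpl-20 and rpl-35. Mitochondrial respiratory chain genes followed with 19 of 39 (odds ratio 7.58, exact adjusted p = 4.44e-08). They were led by cox-5A (signal 1198), cox-6B (signal 291.4) and cox-5B (signal 281). The cox-6B summit lay inside the annotated gene, 153 bp upstream of an internal 5' end. Of 20 subunit genes of the vacuolar ATPase, a proton pump, 9 were bound (odds ratio 6.5, exact adjusted p = 0.000604), led by vha-15 (signal 405), vha-8 (signal 292) and vha-12 (signal 241). Heat shock and chaperone genes had 20 of 53 (odds ratio 4.83, exact adjusted p = 2.27e-06), led by hsp-60 (signal 518), hsp-90 (signal 400.4) and hsp-3 (signal 306). All adjusted p-values for gene lists are from Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 29 lists fixed before the data were examined. Neighbouring genes that share a promoter share a peak, and the 55 ribosomal protein genes were served by 52 peaks. With summits assigned to the nearest gene the odds ratio of ribosomal protein genes was 7.54.

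The pan-neuronal list and that of the DBL-1 pathway, the TGF-beta signal that sets body size, were also above the other genes. Of 18 pan-neuronal genes 7 were bound (odds ratio 5.05, 95% interval 1.66 to 14.3, exact adjusted p = 0.00739), led by snb-1, the synaptobrevin gene (signal 454), unc-18 (signal 181) and egl-21 (signal 158). In the DBL-1 pathway 5 of 13 genes were bound, namely sma-9, sma-3, sma-10, sma-2 and adt-2 (odds ratio 4.96, 95% interval 1.27 to 17.2, exact adjusted p = 0.0304). Signal was 209 at sma-9, 150.4 at sma-3 and 138 at sma-10. The call for the DBL-1 pathway was lost in 6 of 7 alternative settings, with an odds ratio of 3.65 in replicate 2 alone (exact adjusted p = 0.0926), 2.43 in replicate 1 alone (0.299), 5.01 above the median signal and 4.62 with the narrow promoter window.

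Chemoreceptor, C-type lectin, F-box and neuropeptide gene families were bound less often than other genes. Chemoreceptor genes had 18 of 1364 (1.32%, odds ratio 0.0986, exact adjusted p = 5.12e-47), led by sre-50 (signal 630.3), sri-5 (signal 175) and srh-2 (signal 144). C-type lectin genes had 1 of 240, clec-126 (signal 75.9, odds ratio 0.0327, exact adjusted p = 1.71e-10), with an odds ratio of 0.101 in replicate 1 alone. F-box protein genes had 10 of 322 (odds ratio 0.25, exact adjusted p = 9.03e-07), led by fbxb-85 (signal 302), fbxa-90 (signal 218) and fbxc-19 (signal 200.1). Neuropeptide genes had 5 of 140, namely ins-39, nlp-31, nlp-34, nlp-4 and nlp-36 (odds ratio 0.292, exact adjusted p = 0.0066), with an odds ratio of 0.178 in replicate 2 alone. A single peak with a signal of 96.5 served both nlp-31 and nlp-34.

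**Figure D4:**
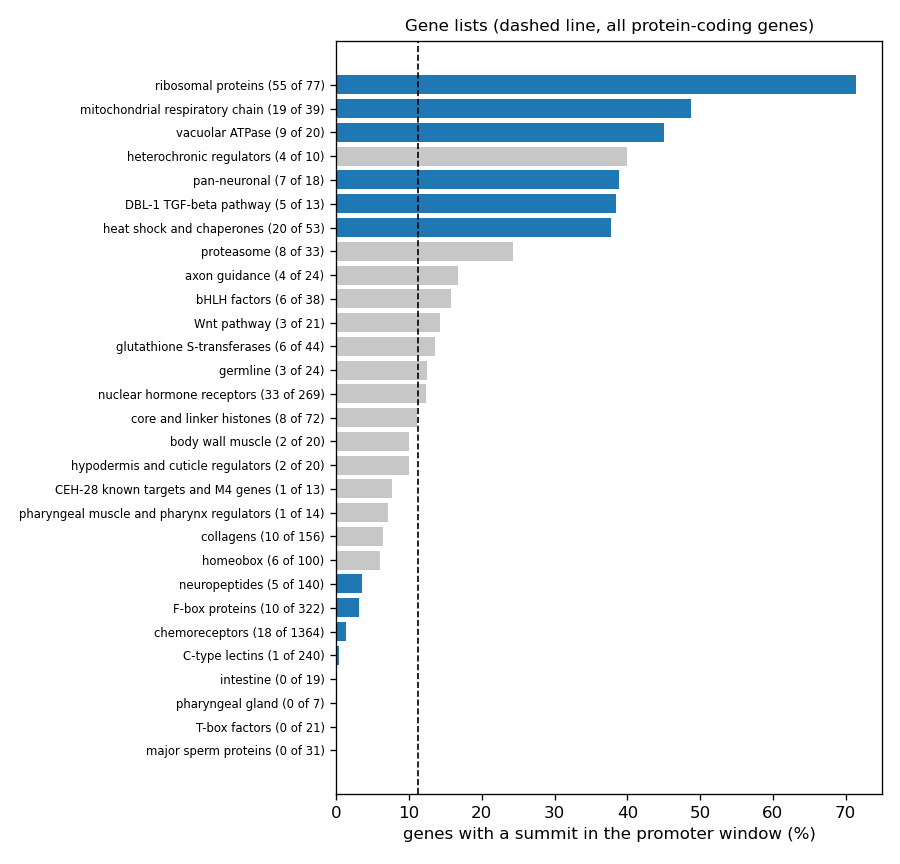
Share of each gene list (%) with a summit in the promoter window, with bound and total members in parentheses. Blue bars passed an adjusted p of 0.05 and grey bars did not, and the dashed line is the share of all protein-coding genes, 11.2%.

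The other lists did not pass the threshold. Heterochronic regulators, which time larval development, had 4 of 10 bound (exact adjusted p = 0.0501), namely lin-28 (signal 176), lin-66 (signal 175.9), alg-1 (signal 144) and lin-14. Proteasome genes had 8 of 33 (exact adjusted p = 0.0638), led by rpn-3 (signal 244), rpn-11 (signal 194) and pbs-1 (signal 143). These lists passed in 6 and 4 of 7 alternative settings, and collagens and major sperm proteins passed as deficits in 2 and 1. Families of regulatory genes gave no call. Nuclear hormone receptor genes had 33 of 269, led by nhr-49 (signal 630.3), nhr-92 (signal 515) and nhr-119 (signal 312), and bHLH factors had 6 of 38, led by aha-1 (signal 331), hlh-11 (signal 223) and mml-1 (signal 138). Homeobox genes had 6 of 100, led by ceh-100 (signal 196), ttx-1 (signal 114) and ceh-7 (signal 97.8), and T-box factors 0 of 21. The ceh-100 peak overlapped no peak of the replicate 1 list, and its partner in replicate 2 ranked 1006. Core and linker histone genes had 8 of 72, led by his-37 (signal 377) and by his-67 and his-68, which shared a peak (signal 141). In replicate 1 alone the odds ratio of the histone list fell from 0.99 to 0.603, and that of the homeobox list from 0.504 to 0.336. Collagen genes had 10 of 156, led by col-38 (signal 135), col-104 (signal 112) and col-71 (signal 102).

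Among signalling and tissue lists, axon guidance had 4 of 24, namely unc-76 (signal 122), unc-40 (signal 114), unc-34 (signal 112) and unc-33. The Wnt pathway had 3 of 21, wrm-1 (signal 197), sys-1 (signal 95.6) and lit-1 (signal 72.1). Germline genes had 3 of 24, cgh-1 (signal 145), mes-3 (signal 131) and mes-2 (signal 94.7). Glutathione S-transferase genes had 6 of 44, led by gst-20 (signal 112), gst-42 (signal 98.6) and gst-43 (signal 71.9). Body wall muscle had 2 of 20, dim-1 (signal 106) and act-4 (signal 75.3), and hypodermis and cuticle regulators 2 of 20, lin-26 (signal 76.9) and nhr-23 (signal 68.0). The list of pharyngeal muscle and pharynx regulators had 1 of 14, peb-1 (signal 84.3). No member was bound among 19 intestine, 7 pharyngeal gland and 31 major sperm protein genes. Some of these lists depended on the replicate, with an odds ratio of 0.455 for intestine and 2.74 for axon guidance (1.58 in the reported setting) in replicate 2 alone. Adjusted p-values of the lists without a value above ranged from 0.0966 to 1.

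Genes known as CEH-28 targets or expressed in M4 did not differ detectably from other genes. Of 13 such genes 1 (7.69%, against 11.2% of all protein-coding genes) had a summit in its promoter window, snb-1, with a peak on chromosome V from 6656791 to 6657095 (signal 454, rank 214). The other genes, ceh-34, dbl-1, flp-21, ceh-28, egl-17, flp-2, flp-5, ser-7, cha-1, unc-17, zag-1 and eya-1, had none (list odds ratio 0.66, 95% interval 0.0154 to 4.46, exact adjusted p = 1). Around egl-17, a fibroblast growth factor gene on X, a thresholded peak ran from 489792 to 490191 (signal 82.8, rank 2579). Its summit lay in an intron, 218 bp downstream of an annotated 5' end and so just outside the promoter window, which ended at 200 bp. The highest peak around egl-17 ranked 2670 in replicate 1 and 2849 in replicate 2. Within 2000 bp of dbl-1, on chromosome V from 6758135 to 6760418, there was no peak in the thresholded, pooled or replicate 1 lists, and the replicate 2 list had 1 at rank 15570. A summit in a whole larva gives no cell of origin, so a site used in a single neuron may fall below the threshold of the list.

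At the locus of the tagged gene itself there was no thresholded peak. Within 2000 bp of ceh-28, on X from 13074673 to 13076092, the pooled and replicate 2 lists also had 0 peaks, and the replicate 1 list had 1, from 13072832 to 13073235, with a signal of 12.1 at rank 19650 of 30000. Around unc-119, on chromosome III from 10902641 to 10908935, the thresholded list had 0 peaks and the pooled list 7, the highest with a signal of 35.2 at rank 8652. In the replicate lists the highest peak near unc-119 ranked 7752 in replicate 1 and 7966 in replicate 2.

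The share of genes with a summit within 500 bp of the gene body did not differ detectably between non-coding RNA and protein-coding genes. It was 14.4% for protein-coding genes (2885 of 19973). The counted span includes the gene body and so grows with gene length, for which no adjustment was made. Equal shares therefore need not mean an equal density of summits. The share was 12.7% for 612 tRNA genes (odds ratio 0.865, 95% interval 0.671 to 1.10), 17.8% for snRNA genes, with 23 bound (1.29, 0.780 to 2.04), 15.3% for 346 snoRNA genes (1.07, 0.782 to 1.44) and 10.7% for 261 miRNA genes (0.712, 0.462 to 1.06). By Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over these classes, 0 passed the threshold, and 0 had an unadjusted p under 0.05 (lowest adjusted p = 0.355). Deficits were called in other settings. For tRNA genes they were in replicate 1 alone (odds ratio 0.632, exact adjusted p = 0.00213) and in the peaks above the median signal (0.578, exact adjusted p = 0.0174). For miRNA genes a deficit was called within 200 bp (0.246, exact adjusted p = 3.71e-05). There 2.68% of miRNA genes and 10.1% of protein-coding genes had a summit. Without an adjustment for gene length, such deficits need not mean a lower density of summits.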

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

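The replicate overlap, the replicate correlation, the promoter share, the lower promoter share of strong peaks and the arm share of all summits kept their direction and stayed past the threshold in every alternative run, as did the enrichment of AATCGAT and of GCGCAGGG, which were tested after the data were examined. Replicate overlap ranged from 65.8% to 81.8%, rho from 0.59 to 0.76 and the promoter share from 42.2% to 63.8%. The X deficit did not hold in every setting. With 1 replicate the X share was 14.5% to 16.5%, above the median signal it was 14.5%, and against promoter sequence the share of 15.6% lay above the background. The odds ratio of TYAAGTG was 0.718 to 0.893 with 1 replicate, 0.684 above the median signal, 0.861 with 25 bp, 0.845 with 100 bp and 0.423 against promoters without a peak, where AATCGAT had 18.2. Called classes of non-coding RNA genes, 0 in the reported setting, were 0 to 1 with 1 replicate, 1 above the median signal and 1 within 200 bp. Of 10 gene lists called, 9 were called in all 7 alternatives. Their odds ratios moved by over 1.5 times for C-type lectins (0.0338 to 0.101) and neuropeptides (0.178 to 0.298) with 1 replicate. The same held with the nearest gene for ribosomal proteins (7.54) and heat shock (3.07), and above the median signal for pan-neuronal (8.37), respiratory chain (5.03), neuropeptides (0.119) and C-type lectins (0). It held with the narrow window for chemoreceptors (0.0498) and neuropeptides (0.149), and with the wide one for C-type lectins (0.0995). Shifts give a ratio to their mean, another measure. Lists that were not called changed side of an odds ratio of 1. With 1 replicate, body wall muscle had 1.43 to 1.45, hypodermis and cuticle regulators 0.426 to 2.73, the Wnt pathway 0.862 to 1.35 and glutathione S-transferases 0.591 to 1.55. Above the median signal, the Wnt pathway had 0.833, glutathione S-transferases 0.387, nuclear hormone receptors 0.984 and CEH-28 targets 1.39. With the narrow promoter window the Wnt pathway had 0.519 and germline 0.944, and with the wide one germline had 0.849 and glutathione S-transferases 0.939. With the nearest gene, body wall muscle and hypodermis and cuticle regulators both had 1.16. Fewer peaks entered the setting above the median signal, and the cause of the other changes was not tested. Without read depth, a site missing from the lists cannot be separated from one sequenced too little.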

Other observations

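At promoters of ribosomal protein genes AATCGAT was less frequent than at other bound promoters, a comparison chosen after the data were examined. AATCGAT lay at 3 of 52 ribosomal protein promoter summits (5.77%) and at 468 of 1811 other promoter summits (25.8%), an odds ratio of 0.176 (95% interval 0.0349 to 0.549, Fisher's exact test, two-sided, p = 0.000497). AATCRAT lay at 8 of the 52 (15.4%), against 38.5%, and it was also rarer in their flanks (3.85%, against 9.34% for all promoter summits), so that the odds ratio over flanks was 4.50 (95% interval 1.13 to 21.5, exact p = 0.0212), against 5.91. In other called lists the sequence was uneven. It lay at the summits of 5 of 9 bound vacuolar ATPase genes, 4 of 7 pan-neuronal genes, 3 of 19 respiratory chain genes and 1 of 20 heat shock and chaperone genes, differences that were not tested.

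In the tests that follow, those of tandem repeats, of another tagged protein, of GC content and of AATCRAT near ribosomal protein summits were chosen after the related results had been seen. The other tests of AATCGAT had their bounds written before their values were seen, but the sequence itself came from the scan of these summits. The design has 1 group, so no biological explanation was tested.

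AATCGAT at peak summits is unlike the sequence known for NK-2 class proteins and resembles that of CUT class homeodomain proteins. Tandem repeats that reach beyond the summit window do not account for it, since in 2222 peaks with no copy from 51 to 449 bp to either side the odds ratio was 11.9 (95% interval 9.67 to 14.8), or 4.33 (3.78 to 4.96) against the flanks of all peaks, as the filter lowered the flank share from 6.94% to 2.63% too. Nor was it limited to the promoter windows of annotated protein-coding genes, as summits outside them gave an odds ratio of 8.08 (95% interval 6.95 to 9.42). Promoters beyond these windows, those of non-coding genes and other open chromatin were not set apart, so signal of open chromatin was not excluded. That another tagged protein was in the strain may be asked because ceh-28 had no thresholded peak, but 19.6% of protein-coding genes had fewer pooled peaks in the 40 kb around them than ceh-28, and 88.6% had fewer than ceh-48, the highest of 6 ONECUT genes (ceh-44, a listed CUT gene of another type, had no match), and neither value met the bounds set for a transgene locus. This remains open, as do shorter repeats, binding through partner proteins and sites bound by many factors, which were not tested.

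GCGCAGGG in the strongest X peaks is the core of a sequence known from recruitment sites of the dosage compensation complex on X. The GC content of X peaks does not account for it, since among X peaks of 40% to 55% GC the odds ratio was 35.1 (95% interval 4.70 to 1570, exact p = 7.91e-06). Within 50 bp of the summit 0 of 2981 autosomal peaks carried GCGCAGGG. The overlapping sequence CGCGCAG was not limited to X. It lay at 23 of 550 X summits (0 of 1100 flanking windows) and at 22 of 2981 autosomal summits (16 of 5962 flanking windows). Its autosomal odds ratio was 2.76 (95% interval 1.38 to 5.64, Fisher's exact test, two-sided, p = 0.00275). A candidate explanation is that the X peaks with GCGCAGGG lie at such recruitment sites, a hypothesis that came from the same data, and whether these sites give signal with other tagged proteins was not tested.

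Clusters of ribosomal protein genes along the gene order do not account for their promoters with peaks. Of 10000 shifts of list membership along that order, 0 gave as many as 55 bound members, with 8.62 on average. The shifts do not keep promoters shared with genes outside the list. With summits assigned to the nearest gene the odds ratio fell from 20.3 to 7.54, still an excess (Fisher's exact test, adjusted p = 1.39e-13). AATCGAT was absent within 50 bp of 49 of the 52 summits and within 200 bp of 41, so most of these peaks had signal with no copy near the summit. Whether AATCGAT is more frequent there than in flanking sequence cannot be told. The odds ratio was 6.23 with a 95% interval of 0.486 to 334. This interval met the bound for no excess, written before this test but after the scan had found AATCGAT. It is wide enough to hold both outcomes. Nor can AATCRAT as the source of the signal be told apart from its absence, since 44 summits lacked it within 50 bp but 59.6% of the 52 peaks had it within 200 bp (95% Wilson interval 46.1% to 71.8%). Signal common to highly transcribed genes in such experiments was not tested and remains open, for the other lists with an excess too.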
